A study of Mus musculus with 23 samples.

How the data were processed

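The series holds Agilent one-colour whole mouse genome arrays of RNA from cultured B cell lymphoma lines of Atm knockout mice and from tumour-free spleens of Atm knockout and Atm wild-type mice. All mice lacked Cd3e and were of a mixed strain background. Per the labels, the lines were established from spleens that carried tumours and were grown in suspension, and the RNA had an integrity number above 8. There were 23 arrays of 22 samples, namely 9 lymphoma lines (10 arrays), 6 knockout spleens and 7 wild-type spleens (4 male and 3 female). The text of the design counts each of the 10 lymphoma arrays as a line while the title of 1 array marks it as a repeat, so the arrays of that line, number 8 here, were averaged. Groups and sexes were taken from the labels before the data were examined, as were the comparisons, the gene lists and the alternatives, except where the closing section says so.

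The deposited scanner files hold spot intensity values that, per the file headers, Agilent Feature Extraction 10.7.1.1 wrote after it had subtracted the local background and corrected the signal of each spot. The deposited value table holds log2 values, which were checked against the scanner files. Each of its arrays had a correlation of 1 with the log2 processed signal, and all 41174 of its 41174 probes had a median of 0, so the table is the same signal after scaling and after centring of each probe. The scanner files were used for all results, and the value table served as an alternative.

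On each array 1639 control spots were left out and 43379 spots remained, from which 1556 spots over all arrays were dropped because the scanner's flags marked them as uneven or as outliers among replicate spots. No spot was left out for saturation (0). Spots of the same probe were averaged. Each array was scaled to its 75th percentile and taken to log2. The array names only probes, so symbols came from the RefSeq accessions of the probes, joined to a RefSeq gene table of assembly GRCm38.p6. The order of genes in that table was used to find neighbouring genes, and no coordinates are given. Of the 41174 probes, 26690 matched a symbol and 14484 did not, which gave 18217 genes. A gene was tested if its probe was well above background, by the scanner's own test, in at least 6 of 22 samples, and its probe with the highest mean represented it. This left 13743 genes, 4983 of them with more than 1 tested probe, and 7515 probes within the filter had no symbol and were not used here.

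Differences were fitted with limma 3.58.1 in R 4.3.3, after reading with the data.table package, version 1.17.8. The comparisons of the lymphoma lines with each group of spleens came from a fit of the 3 groups with 1 value per sample. The genotype comparison came from a fit of the 13 spleens with terms for genotype and sex, which also gave the sex comparison. Standard errors and p are those of the moderated model, p were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists tested. Lists were scored by the median log2 difference of their members, and single samples by the mean level of the members. Of 29 lists fixed beforehand, 27 had at least 5 tested members. The sex-linked list had 4 tested members and served to check the labelled sex, and the immunoglobulin list had 1, Jchain, because 3 of its 18 members matched a probe. Over all lists 54 members matched no probe. Where most samples of a group were not well above background for a gene, its level on each array was raised to at least the lowest level of any probe well above background on that array, and the fold against this level is given as a lower bound. Where only some samples were not, the number that were is given and the log2 difference is as fitted. The list medians given with bounds hold at their bound only the genes with no array of a group well above background.

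The genes named follow a rule. They are the 12 largest increases and 12 largest decreases of each lymphoma comparison among called genes whose groups did not overlap, the 10 called genes of each direction with the lowest adjusted p between genotypes, the called members of each list with the largest changes (up to 3 per direction for the NF-kB, DLBCL and p53 lists and 2 for the others), and a fixed set that includes Atm, Cd3e, Myc, Bcl6, Irf4, Trp53, Cdkn1a and sex-linked genes. Unnamed clone and predicted genes were passed over, and not every gene the rule gives is described. The order and share of changes differ with the scaling, so the median of all genes is given with each comparison.

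The precision was tested on simulated data, in which 100 genes per size of change were shifted in values drawn with each gene's pooled spread. At a log2 change of 1 the fits recovered 68% of changed genes for lymphoma lines against knockout spleens, 67% against wild-type spleens and 72% between genotypes, and at a change of 2 they recovered 93%, 93% and 92%. Of the genes called, 5.64%, 6.63% and 6.25% were unchanged ones. In the list test a shifted cell cycle list was recovered and 0 of the 26 other lists were called. Genes were drawn independently, while the estimated correlation of the cell cycle list was 0.71 in the lymphoma comparisons. The draws also gave the lines no larger spread than the spleens. The simulation therefore cannot vouch for list calls among correlated genes.

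The alternatives were a normexp background correction (offset 50) or the processed signal with quantile normalisation, centring on array medians, the value table, no filter or a stricter filter on dim probes, the mean of all probes or each probe alone, slide as a random block or a fixed term, array weights by group, a trended and robust moderation, both arrays or only the first array of line 8, only the groups compared, no lines from the lymphoma-only slide, female spleens only, no sex term, and 1 fit of all groups without a sex term for the genotype comparison. Wild-type replicate 2 and lines 3, 5, 7 and 8 were also left out, 1 at a time, and no knockout spleen was. The correlation of the lymphoma comparisons was set against 20 simulations with shared lines, no effect and the same spread in lines and spleens. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The study's title concerns NF-kB dependence, for which no treated or control-treated sample is among the arrays, so dependence was not analysed here.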

Results

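RNA from 22 mouse samples was measured on 23 one-colour Agilent whole-genome arrays. All mice lacked Cd3e, which encodes a chain of the T cell receptor complex. The samples were 9 B cell lymphoma lines grown in suspension culture from Atm knockout mice, 6 tumour-free spleens of Atm knockout mice and 7 spleens of Atm wild-type mice. Atm encodes the kinase that signals DNA double-strand breaks. Lymphoma line 8 was measured on 2 arrays, which were averaged. All 6 knockout spleens came from females, while the wild-type spleens came from 4 males and 3 females. Spots well above background made up 54.9% to 62.3% of the spots on the arrays of the lines, 62.6% to 67.7% for knockout spleens and 61.7% to 66.9% for wild-type spleens. The 75th percentile of the processed signal was 491 to 788 in the lines, 668 to 896 in knockout spleens and 570 to 832 in wild-type spleens. The arrays lay on 6 slides, and 1 of these slides held only lymphoma lines. Log2 levels below are relative to the 75th percentile of each array, and 13743 genes were tested.

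The Atm probe separated the groups without overlap. Its log2 level was -0.67 to 0.00 in wild-type spleens, -2.69 to -2.07 in knockout spleens and -4.38 to -2.77 in the lines. A second Atm probe had a mean of -1.81 ± 0.24 (SD, n = 7) in wild-type spleens, -3.61 ± 0.16 (SD, n = 6) in knockout spleens and -4.03 ± 0.38 (SD, n = 9) in the lines. Cd3e was between -4.65 and -3.86 in all 13 spleens and between -3.30 and -1.22 in the lines, and its probe was well above background in all of these samples. The sources used here do not give which part of either gene was deleted, so the probes show transcript levels and not the genotype. Xist, which silences the X chromosome, and the Y-linked genes Ddx3y, Eif2s3y and Kdm5d matched the labelled sex in all 13 spleens.

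**Figure D1:**
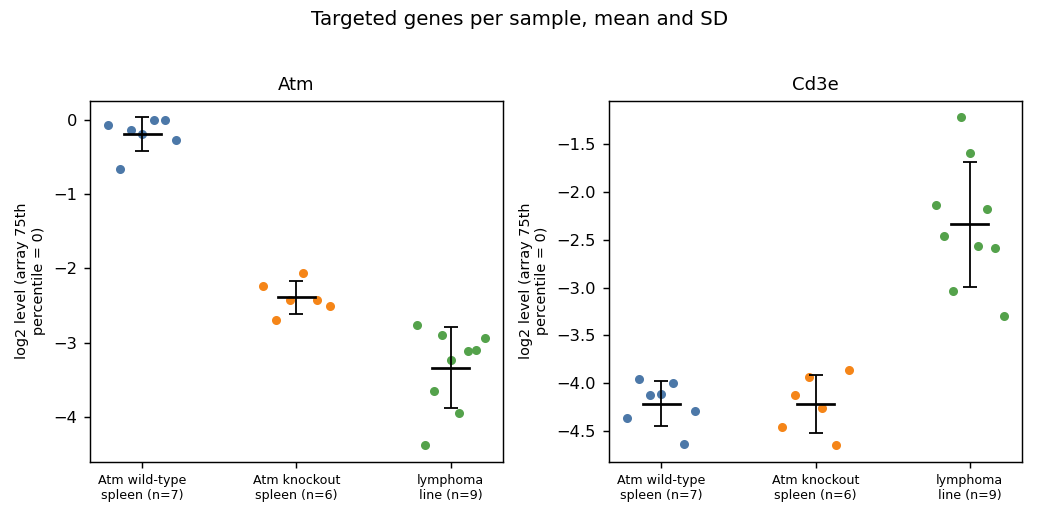
Log2 level of Atm and Cd3e (vertical axes, array 75th percentile = 0) in each sample of the 3 groups, with points for samples, a long bar for the mean and whiskers for the SD. Atm lies between -0.67 and 0.00 in wild-type spleens, between -2.69 and -2.07 in knockout spleens and between -4.38 and -2.77 in lymphoma lines, and Cd3e is higher in the lines than in any spleen.

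The comparison of lymphoma lines with Atm knockout spleens sets tumour cells beside tumour-free tissue of the same Atm label, and the study's title asks about B cell lymphomas that depend on NF-kB. In the lines, 5710 genes rose and 3971 fell, and 2455 and 2795 of these differed at least 2-fold (5878 and 2109 with median centring, 1390 and 1771 with normexp). Among genes whose groups did not overlap, the largest increase was in Plch2, a phospholipase C, with a mean of 6.88 ± 1.06 (SD, n = 9) in the lines and -4.58 ± 0.81 (SD, n = 6) in the spleens. The log2 difference was 11.45 ± 0.41 (SE, limma adjusted p = 3.53e-16). Cth, an enzyme that makes cysteine, rose by 7.92 ± 0.22. Gnaz, a G protein subunit, rose by 7.41 ± 0.28.

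Where most samples of a group were not well above background, that group's level is only an upper limit and the fold is given as a lower bound. On this basis Mgarp, a mitochondrial protein, was at least 865-fold higher in the lines and Cd109, a membrane-anchored regulator of TGF-beta signalling, at least 680-fold. Tmem45a (8 of 9 lines well above background) was at least 245-fold higher, Stc2, a secreted glycoprotein, at least 228-fold, Rnf183, a ubiquitin ligase, at least 200-fold and Sntg2 (8 of 9 lines) at least 53.2-fold. Myom2, a muscle structural protein, was at least 452-fold higher and Wwtr1, a transcriptional coactivator of the Hippo pathway, at least 132-fold, each well above background in 2 of 6 spleens. The largest such decreases were in products of granulocytes, erythroid and cytotoxic cells. S100a9 was at least 12430-fold lower, S100a8 at least 2852-fold, Ltf at least 2520-fold, Camp at least 2456-fold, Lyz1 at least 2267-fold and Ngp at least 1524-fold, and each was well above background in at most 2 of 9 lines. Hba-a1, a globin measured in all 9 lines, fell by 11.84 ± 0.63. The macrophage protein Chil3 fell by 12.10 ± 0.57 and was well above background in 5 of 9 lines. The granzyme Gzma was at least 1014-fold and the myeloid receptor Treml4 at least 924-fold lower, each well above background in 1 of 9 lines.

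Among 47 measured NF-kB target genes, 15 rose and 27 fell. The increases were led by Cd80, a costimulatory ligand (3.19 ± 0.17, adjusted p = 3.33e-13), Il10, an anti-inflammatory cytokine (2.98 ± 0.38), and Ebi3, a cytokine subunit (2.61 ± 0.20). The decreases were led by the chemokines Ccl5 (-12.12 ± 0.53), Ccl4 (at least 2043-fold) and Ccl3 (at least 1006-fold), which were well above background in 6, 2 and 1 of 9 lines. Ccl5 and 1 other member of this list are also in a cell type marker list, and the NK cell and macrophage markers fell in the same comparison (below). The list's median log2 difference was -0.55, against 0.18 for all genes, with adjusted p = 0.00142 in the list test and adjusted p = 0.215 with an estimated correlation. Centring each array on its median turned the list's median to 0.11, still -0.73 relative to all genes. The median was -0.54 with slide as a fixed term and -0.83 to -0.04 within the 5 slides that hold both groups.

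Of 34 NF-kB pathway components, 9 rose and 14 fell, and the list did not pass (median -0.10, or 0.55 with median centring, adjusted p = 0.131). It was called lower with quantile normalisation (-0.38, adjusted p = 0.00745), with normexp (-0.33, adjusted p = 0.00428) and with no filter on dim probes (adjusted p = 0.0495). The receptors Tnfrsf13b and Tnfrsf13c, which bind the B cell survival factor BAFF, rose by 1.81 ± 0.21 and 1.64 ± 0.13, and the endotoxin receptor Tlr4 by 1.03 ± 0.16. Tnfrsf1a, a TNF receptor, was at least 240-fold lower and well above background in 1 of 9 lines. The lymphotoxin receptor Ltbr was at least 75.8-fold lower, and the RNA sensor Tlr7 (8 of 9 lines well above background) fell by 6.66 ± 0.64. Among 28 genes of activated B cell (ABC) type diffuse large B cell lymphoma (DLBCL), 17 rose and 8 fell (median 0.53, adjusted p = 0.179). Fut8, a fucosyltransferase, rose by 2.73 ± 0.18, and the transcription factor Batf by 2.42 ± 0.15. Il6 (at least 45.0-fold, 1 of 9 lines well above background), the ectonucleotidase Entpd1 (-3.94 ± 0.57, 8 of 9 lines) and the pro-death factor Bmf (-0.98 ± 0.23) fell, but Bmf was -0.33 and did not pass with median centring. Irf4, which drives plasma cell fate, fell by 0.63 ± 0.21 (adjusted p = 0.0115), but its difference was 0.025 with median centring. Of 20 genes of germinal centre (GCB) type DLBCL, 9 rose and 6 fell (median 0.31, adjusted p = 0.964). The ABC list shares 12 of its 29 members with other lists, and the GCB list 8 of 23.

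Single germinal centre genes went both ways in the lines. The transcription factor Mef2b rose by 6.99 ± 0.18 (127-fold) and Rgs13, a regulator of G protein signalling, by 6.58 ± 0.23. S1pr2, a receptor that confines B cells to germinal centres, rose by 3.98 ± 0.23, and Bcl6, the germinal centre master regulator, by 1.77 ± 0.31. Mybl1 (8 of 9 lines well above background) was at least 4.82-fold higher. Lmo2 (-3.35 ± 0.53), Eml6 (-3.11 ± 0.74, 8 of 9 lines) and the membrane ligand Efnb1 (-3.13 ± 0.79, 8 of 9 lines) fell, and Gcsam was at least 1.93-fold lower. Of 15 germinal centre B cell markers, 8 rose and 4 fell, and the list did not pass (median 0.93 above that of all genes, adjusted p = 0.115). Among 27 B cell markers, 9 rose and 13 fell (median -0.22, or 0.44 with median centring, adjusted p = 0.191). That list was called lower with quantile normalisation (median -0.62, adjusted p = 0.0147) and with normexp (-0.60, adjusted p = 0.00913). Spib rose by 1.20 ± 0.17, while the low-affinity IgE receptor Fcer2a (at least 671-fold, 1 of 9 lines well above background) and the complement receptor Cr2 (-7.25 ± 0.49, 8 of 9 lines) fell. Plasma cell markers went both ways, 8 up and 6 down of 16 (median 0.29, mean -0.11, adjusted p = 0.520). Derl3 and Mzb1, proteins of the secretory pathway, rose by 3.69 ± 0.22 and 3.02 ± 0.12, while Tnfrsf17 (at least 33.6-fold, 2 of 9 lines well above background) and Sdc1 (-3.38 ± 0.81, 8 of 9 lines) fell.

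**Figure D2:**
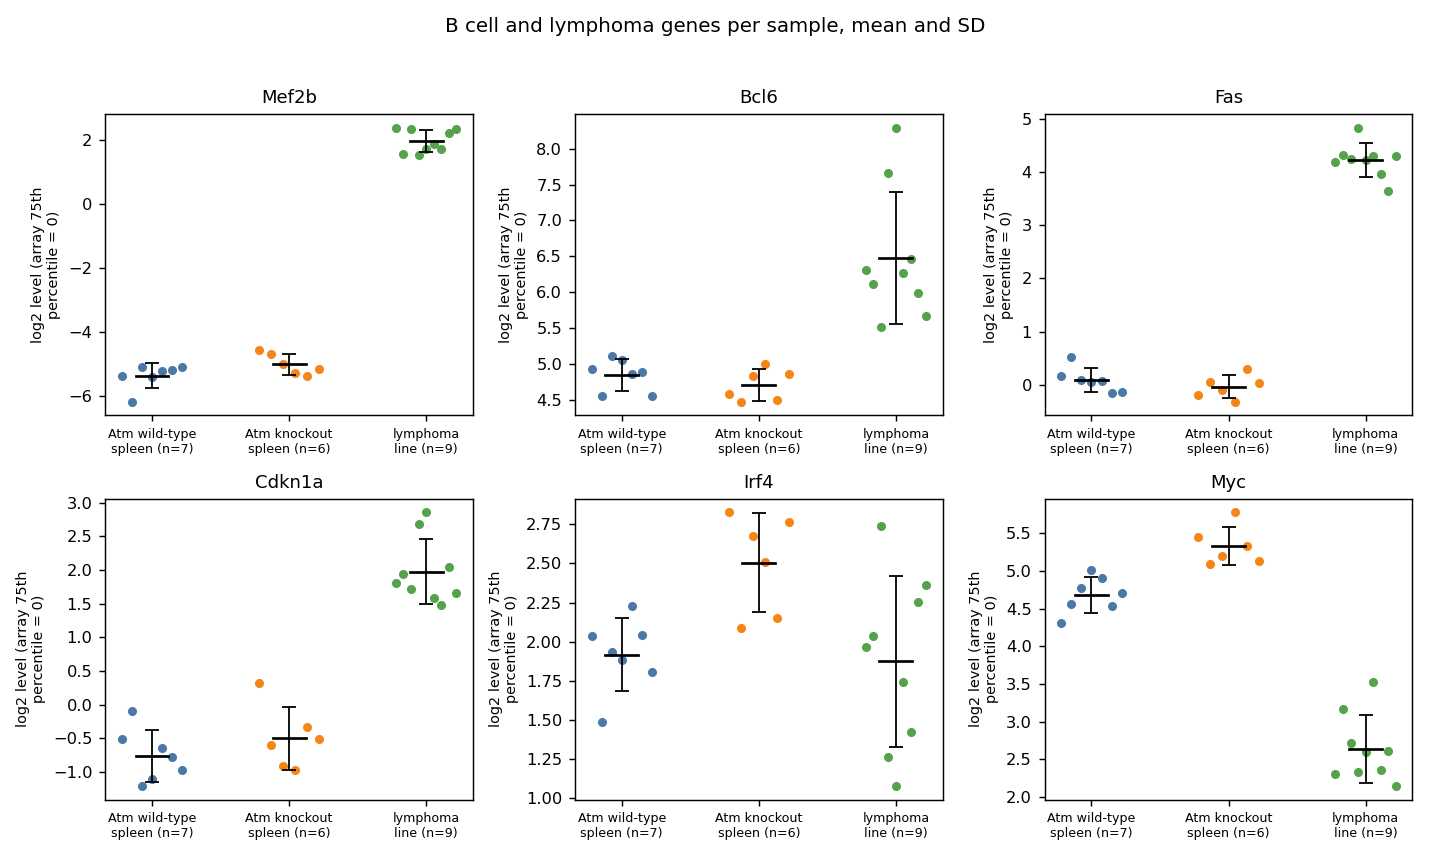
Log2 level (vertical axes, array 75th percentile = 0) of Mef2b, Bcl6, Fas, Cdkn1a, Irf4 and Myc in each sample of the 3 groups, with points for samples, a long bar for the mean and whiskers for the SD. Mef2b, Bcl6, Fas and Cdkn1a are higher and Myc lower in every lymphoma line than in every spleen, while Irf4 overlaps between the groups.

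Among 31 p53 target genes, 22 rose and 4 fell in the lines (median 0.81, adjusted p = 0.00381, and 0.0619 as adjusted p with an estimated correlation). The death receptor Fas rose by 4.26 ± 0.14 (19.1-fold), Phlda3 by 3.52 ± 0.29, Zmat3 by 3.21 ± 0.17 and the cell cycle inhibitor Cdkn1a by 2.48 ± 0.23. Plk2 (-4.30 ± 1.54, 6 of 9 lines well above background), Sesn1 (-3.15 ± 0.19) and Btg2 (-2.53 ± 0.20) fell. Trp53 itself did not pass (-0.09 ± 0.14, adjusted p = 0.587), but with median centring its difference was 0.57 and passed. In the DNA double-strand break response, 21 of 29 genes rose and 2 fell (median 0.78, adjusted p = 0.00189, and adjusted p = 0.253 with an estimated correlation). The repair genes Fancd2 and Brca1 rose by 2.44 ± 0.29 and 2.16 ± 0.25. The members that fell were Atm (-0.94 ± 0.20, but -0.29 and not past the threshold with median centring) and Dclre1c (-0.56 ± 0.13), a nuclease of V(D)J recombination, which was 0.092 with median centring and opposite at another probe.

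Proliferation and metabolic genes were higher in the lines. Of 39 cell cycle genes, 36 rose and 0 fell, with a median of 1.80 (adjusted p = 4.19e-07, and adjusted p = 0.364 with an estimated correlation), and the medians within slides ran from 0.71 to 2.31. Ccnb1, a mitotic cyclin, rose by 2.77 ± 0.30 and the mitotic transcription factor Foxm1 by 2.74 ± 0.25. All 23 cholesterol synthesis genes rose, with a median of 2.80 (adjusted p = 7.92e-12, and adjusted p = 0.0619 with an estimated correlation), led by Sqle (3.96 ± 0.13) and Fdps (3.80 ± 0.16). Of 20 glycolysis genes, 15 rose and 2 fell (median 2.17, adjusted p = 4.05e-05, and adjusted p = 0.0820 with an estimated correlation). The glycolytic enzymes Aldoc and Tpi1 rose by 4.17 ± 0.52 and 3.86 ± 0.11, and the glucose transporter Slc2a3 fell by 2.73 ± 0.55. Of 37 MYC target and ribosome biogenesis genes, 28 rose and 1 fell (median 0.59, adjusted p = 5.15e-04, and adjusted p = 0.364 with an estimated correlation). Lactate dehydrogenase Ldha rose by 2.18 ± 0.09 and Wdr12 by 1.38 ± 0.10, and the member that fell was Myc itself (-2.70 ± 0.18), from 5.33 ± 0.26 (SD, n = 6) in the spleens to 2.64 ± 0.45 (SD, n = 9) in the lines. This list passed with median centring but missed the threshold with quantile normalisation (median 0.25, adjusted p = 0.0615).

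NRF2 antioxidant genes went both ways, 5 up and 9 down of 20 (median -0.16, or 0.49 with median centring, adjusted p = 0.225), with Prdx1, a peroxidase, 1.67 ± 0.14 higher and the glutathione transferase Gstm1 lower (-3.58 ± 0.37). In the BCL2 family, 8 rose and 4 fell of 14 (median 0.41, adjusted p = 0.341). The pro-death genes Bbc3 and Bcl2l11 moved apart, by 2.68 ± 0.15 and -3.70 ± 0.67, and the pro-survival gene Bcl2l1 rose by 1.81 ± 0.35. Interferon response genes fell together, 25 of 27 with 0 rising and a median of -2.94 (adjusted p = 1.62e-11). Rtp4 was at least 732-fold and the antiviral synthetase Oas1a at least 353-fold lower, and each was well above background in 2 of 9 lines. Of 15 MHC class II genes, 11 fell and 1 rose (median -1.23, adjusted p = 6.89e-04, and adjusted p = 0.298 with an estimated correlation), with H2-Oa (-3.44 ± 0.40) and H2-DMb2 (-2.12 ± 0.27) among the genes that fell. The MHC class I list did not pass (7 up and 2 down of 18, median 0.14, or -0.20 with quantile normalisation, adjusted p = 0.458). Its chaperone Canx rose by 1.08 ± 0.08 and the proteasome subunit Psmb10 fell by 0.99 ± 0.12.

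Markers of the other cell types of the spleen fell in the lines, which were grown from cultured B lymphoma cells. All 23 NK cell markers (median -7.73, adjusted p = 1.00e-16), all 26 macrophage and monocyte markers (-7.05, adjusted p = 1.55e-16) and all 20 neutrophil markers (-9.42, adjusted p = 8.84e-13) fell. So did 21 of 23 erythroid markers (-7.32, adjusted p = 1.07e-11), 15 of 17 dendritic cell markers (-4.73, adjusted p = 4.92e-08), 14 of 16 megakaryocyte and platelet markers (-4.32, adjusted p = 4.21e-09) and 18 of 27 stromal and endothelial markers (-2.08, adjusted p = 3.28e-05). With the genes below background at their bound, these medians were -7.02, -6.19, -8.23, -6.33, -3.62, -3.84 and -1.13, in the same order. With an estimated correlation the adjusted p was 0.0820 for neutrophil, 0.0927 for erythroid and 0.0619 for stromal markers. The medians were smaller with normexp, where they were -3.61, -4.24, -5.22, -4.16, -1.24, -1.26 and -0.25 in that order. Examples are Alas2, of haem synthesis (at least 1292-fold lower), Vcam1, an adhesion molecule (at least 965-fold), and C1qc, a complement gene (at least 840-fold), each well above background in 1 of 9 lines, and the platelet chemokines Pf4 (at least 158-fold lower) and Ppbp (at least 90.8-fold lower). The exceptions that rose were Tcf4 (2.50 ± 0.19), a transcription factor that B cells also use, in the dendritic cell list, and Cdh5 (1.20 ± 0.27) and Vim in the stromal list. Vim rose by 0.52 ± 0.13 but by 0.02 with quantile normalisation.

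T cell markers fell in 17 of 24 cases and rose in 5 (median -2.77, or -0.96 with normexp, adjusted p = 3.28e-05, and adjusted p = 0.0643 with an estimated correlation). Thy1 was at least 361-fold lower and the kinase Txk at least 193-fold lower. Cd3g, which neighbours Cd3e in the genome and encodes another chain of the same complex, rose by 7.35 ± 0.78, Ctla4, an inhibitory receptor, by 2.72 ± 0.31 and Cd3e by 1.87 ± 0.24. Pro-B and pre-B cell markers fell in 9 of 14 cases and rose in 2 (median -3.67, or -2.93 with bounds and -1.36 with normexp, adjusted p = 0.00486, and adjusted p = 0.138 with an estimated correlation). Cd93 (at least 334-fold, 3 of 9 lines well above background) and Vpreb3 (-6.81 ± 0.80, 8 of 9 lines), a partner of the surrogate light chain, fell. Cecr2 rose by 1.86 ± 0.20 and Smarca4, a chromatin remodeller, by 0.32 ± 0.11, but Smarca4 was -0.17 with quantile normalisation.

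**Figure D3:**
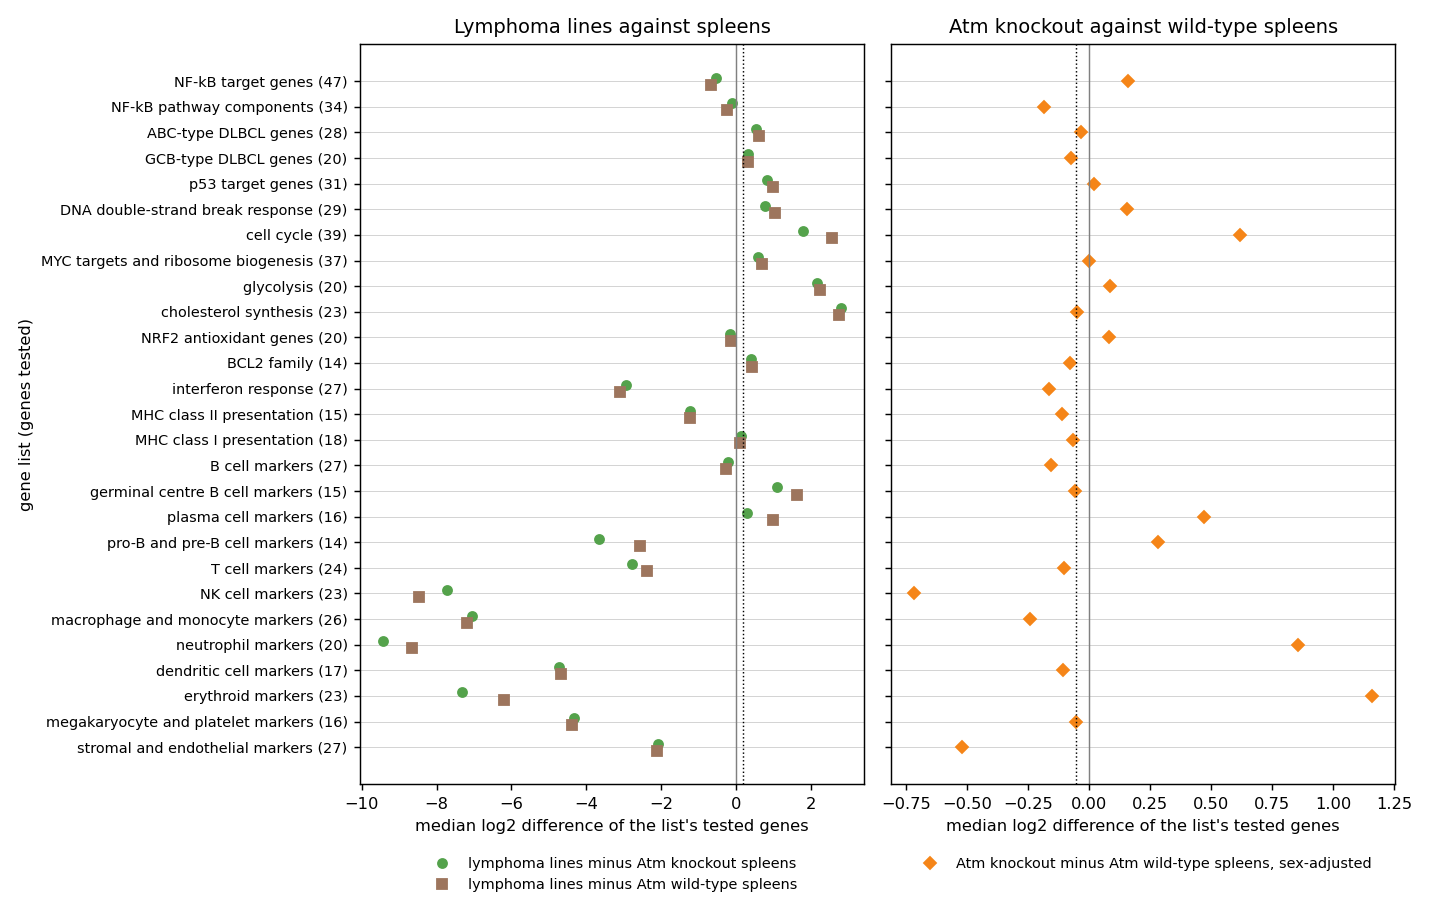
Median log2 difference (horizontal axes) of the tested members of 27 gene lists (vertical axis, number tested in brackets), for lymphoma lines minus knockout spleens (circles) and minus wild-type spleens (squares) on the left and for knockout minus wild-type spleens (diamonds) on the right. The dotted lines mark the median of all genes in the comparisons with knockout spleens (0.18) and between genotypes (-0.05), the NK cell, macrophage, neutrophil and erythroid lists lie lowest on the left, and the horizontal scales of the panels differ.

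These calls come from limma at a Benjamini-Hochberg adjusted p of 0.05, and the list tests from camera with a preset correlation of 0.01. Of the 18 lists that passed, the interferon, NK cell, macrophage, dendritic cell and megakaryocyte lists also passed with an estimated correlation. Adjusted over the list alone, the counts were the same for all lists but glycolysis (16 up) and MHC class I (6 up). The groups did not overlap on any sample for 3313 of the genes that rose and 2312 of those that fell, where chance gives 0.0200% of genes in each direction. The split of calls depends on the scaling, since centring arrays on their medians gave 8691 higher and 2509 lower genes (77.6% higher, against 59.0%) and moved the median of all genes from 0.18 to 0.83. With slide as a fixed term 5828 rose and 4037 fell, and within the 5 slides that hold both groups 96.0% to 98.2% of the called genes kept the pooled direction. The same samples called these genes, so high shares are partly built in. Lines 4 and 5 were the most alike pair of different lines, and whether they are independent samples is not in the labels. Without line 5, 5643 genes rose and 4013 fell. Culture, cell composition and malignancy differ together between lines and spleens.

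The comparison of lymphoma lines with Atm wild-type spleens asks the same of tissue with intact Atm. In it 5550 genes rose and 4245 fell (2633 and 2874 at least 2-fold, 5593 and 2118 with median centring, and 1588 and 1852 with normexp), with a median of 0.14 over all genes. Plch2 rose by 11.77 ± 0.39, Ncan, a proteoglycan, by 8.36 ± 0.36 (6 of 7 spleens well above background), Cth by 8.30 ± 0.21 (6 of 7 spleens) and Timd2 by 7.94 ± 0.22. Mgarp was at least 751-fold higher and Cd109 at least 480-fold, well above background in 1 and 2 of 7 spleens. Tmem45a (8 of 9 lines well above background) was at least 217-fold, Rnf183 at least 177-fold and Klhl13 at least 71.4-fold higher. S100a9 was at least 10972-fold, the matrix protein Tgfbi at least 1343-fold and the NK cell receptor Klrd1 at least 843-fold lower, and they were well above background in 2, 1 and 1 of 9 lines. Atm fell by 3.14 ± 0.19 (adjusted p = 3.45e-12) and Cd3e rose by 1.87 ± 0.23. Mef2b rose by 7.34 ± 0.18, Rgs13 by 6.29 ± 0.22, Ctla4 by 5.18 ± 0.30 (6 of 7 spleens well above background) and Bcl6 by 1.63 ± 0.30, while Myc fell by 2.05 ± 0.17. Irf4 did not pass (-0.04 ± 0.20, adjusted p = 0.863), nor did Trp53 (-0.11 ± 0.13, adjusted p = 0.483), but with median centring they were 0.60 and 0.54 and passed.

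Of 47 NF-kB targets, 14 rose and 25 fell relative to wild-type spleens, with a median of -0.67 (adjusted p = 0.0109, and adjusted p = 0.291 with an estimated correlation). The median was -0.81 relative to all genes, -0.55 with slide as a fixed term and -0.65 to -0.03 within slides. Il10 rose by 4.64 ± 0.36, Cd80 by 3.88 ± 0.16 and Ebi3 by 2.65 ± 0.20, and Ccl5 (-12.40 ± 0.50, 6 of 9 lines well above background), Ccl4 (at least 1337-fold, 2 of 9 lines) and Ccl3 (at least 708-fold, 1 of 9 lines) fell, beside the falls of the NK cell and macrophage markers. NF-kB pathway components rose in 7 and fell in 17 of 34 cases (median -0.24, adjusted p = 0.0428, and adjusted p = 0.338 with an estimated correlation). That call was made in 15 of 20 alternatives. It was lost, among others, with slide as a fixed term (adjusted p = 0.0600) and without lymphoma line 7 (adjusted p = 0.0543). It was also lost with median centring (adjusted p = 0.333), which moved the list's median to 0.41 but left it at -0.37 relative to all genes. Cell cycle genes rose in 37 of 39 cases (median 2.56, adjusted p = 5.12e-10), cholesterol synthesis in 23 of 23 (2.75, adjusted p = 3.91e-11), glycolysis in 17 of 20 (2.25, adjusted p = 1.14e-05), MYC targets in 29 of 37 (0.69, adjusted p = 4.40e-05), break response in 22 of 29 (1.03, adjusted p = 5.60e-04) and p53 targets in 21 of 31 (0.98, adjusted p = 0.00409). With an estimated correlation these adjusted p were 0.282, 0.0651, 0.0654, 0.282, 0.218 and 0.0651. Examples are Fas (4.13 ± 0.14), Cdkn1a (2.74 ± 0.22), Ccnb1 (3.79 ± 0.29), Odc1, of polyamine synthesis (1.91 ± 0.09), Tpi1 (4.09 ± 0.10) and Sqle (4.13 ± 0.13).

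Interferon response genes fell in 25 of 27 cases (median -3.09, adjusted p = 3.91e-11), with Rtp4 at least 847-fold lower (2 of 9 lines well above background) and Oas2 at least 312-fold (1 of 9 lines), and MHC class II genes in 12 of 15 (-1.22, adjusted p = 4.96e-04, and adjusted p = 0.282 with an estimated correlation), with the class II transactivator Ciita at -2.16 ± 0.28. The ABC (16 up and 7 down of 28, median 0.61), GCB (9 and 6 of 20, 0.32), NRF2 (5 and 9 of 20, -0.13, or 0.52 with median centring), BCL2 (8 and 4 of 14, 0.41), MHC class I (5 and 1 of 18, 0.11, or -0.27 with quantile normalisation), B cell (8 and 12 of 27, -0.26, or 0.38 with median centring), germinal centre (8 and 4 of 15, 1.63) and plasma cell (8 and 4 of 16, 0.97) lists did not pass, at adjusted p of 0.143, 0.846, 0.359, 0.359, 0.565, 0.118, 0.107 and 0.137. The B cell list was called lower with quantile normalisation (median -0.68, adjusted p = 0.00588) and with normexp (-0.70, adjusted p = 0.00373). Derl3 rose by 4.53 ± 0.21, Mzb1 by 3.30 ± 0.11 and Ccnd2, a cyclin of the ABC list, by 2.50 ± 0.14. All 23 NK cell (median -8.47), 26 macrophage (-7.18) and 20 neutrophil (-8.65) markers fell, with 15 of 17 dendritic cell (-4.67), 21 of 23 erythroid (-6.19), 15 of 16 megakaryocyte (-4.37), 20 of 27 stromal (-2.12), 17 of 24 T cell (-2.39) and 8 of 14 pro-B and pre-B cell (-2.56) markers. The highest adjusted p of these lists was 0.0322, for the pro-B and pre-B cell markers. With an estimated correlation the adjusted p was 0.109 for neutrophil, 0.152 for erythroid, 0.0651 for stromal, 0.0878 for T cell and 0.261 for pro-B and pre-B cell markers.

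The calls are from the same limma fit. Adjusted over the list alone, the counts were the same for every list. The groups did not overlap for 3291 genes that rose and 2465 that fell, where chance gives 0.00874% of genes in each direction. Median centring gave 8546 higher and 2636 lower genes (76.4% higher, against 56.7%) with a median of 0.78 over all genes. With slide as a fixed term 5718 rose and 4307 fell, and within slides 95.3% to 98.4% of called genes kept their direction. Here too the same samples called the genes, so such shares are partly built in. The 4 male spleens are all in the wild-type group, and the sex of the lines is not in the labels.

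The lists of genes from these comparisons overlapped in 5205 genes that rose and 3725 that fell in both, and 5 genes had opposite calls. Lists drawn independently would share 2305.9 and 1226.6 genes. Because both comparisons use the same 9 lines, the overlap was also counted with 5 lines against knockout spleens and the other 4 lines against wild-type spleens. This gave 4801 genes up and 3427 down in both. Lines 4 and 5 may come from the same mouse or related tumours, so this split does not ensure that the sets of lines are independent. Across genes, which are not independent replicates, the log2 differences had a correlation of 0.98, where the simulation of the shared lines alone gave 0.41. That simulation gave lines and spleens the same spread. The lines varied more, as given next, so 0.41 understates what shared lines alone would give. The spleen groups also differed at few genes (525 of 13743 called), which by itself makes the comparisons alike. The correlation is thus no separate result. The lines differed from each other more than the spleens did. The median SD per gene was 0.44 over the lines, 0.23 over knockout and 0.21 over wild-type spleens, and 85.3% of genes had the larger SD in the lines than in knockout spleens. The correlation between arrays of different lines was 0.943 to 0.986, with a median of 0.959 over 44 pairs, against medians of 0.986 among knockout and 0.985 among wild-type spleens.

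The comparison of knockout with wild-type spleens, adjusted for sex, asks what Atm loss changed before tumours. In knockout spleens 228 genes rose and 297 fell, 81 and 77 of them at least 2-fold (30 and 18 with normexp, 67 and 24 with slide as a fixed term, 186 and 35 without a sex term). Plasma cell genes were among the increases with the lowest adjusted p. Jchain, which joins IgM and IgA chains, rose by 1.98 ± 0.17 (limma adjusted p = 2.77e-04), the survival receptor Tnfrsf17 by 2.12 ± 0.23 and the secretory transcription factor Bhlha15 by 1.01 ± 0.10. Of 16 plasma cell markers, 5 rose and 0 fell, and 12 rose when adjusted over the list alone (median 0.47, adjusted p = 3.30e-13, and adjusted p = 0.0529 with an estimated correlation). The median was 0.62 with slide as a fixed term and 0.36 to 0.59 within slides. Other increases were Enkur (2.30 ± 0.25), Mpzl2, an adhesion protein (2.15 ± 0.22), the neuropeptide gene Calca (2.14 ± 0.24, 6 of 7 wild-type spleens well above background), the phosphodiesterase Pde4d (1.58 ± 0.18), Zscan18 (1.31 ± 0.14), the early response transcription factor Egr4 (1.19 ± 0.12) and the stress gene Gadd45b (0.88 ± 0.10). Apart from Atm, which fell by 2.30 ± 0.16 (adjusted p = 4.64e-05), the decreases with the lowest adjusted p were Fam219b (-0.89 ± 0.11), Rasgef1a (-0.92 ± 0.12), Fkbp10, of collagen folding (-1.06 ± 0.14), Zfp566 (-0.88 ± 0.11), Clec4g (-1.08 ± 0.15), Zfp3 (-0.83 ± 0.12), Fkbp5, a glucocorticoid-induced chaperone (-2.06 ± 0.30), Mcts2 (-0.82 ± 0.12) and P3h4, of collagen modification (-1.19 ± 0.17). The samples of the genotypes overlapped for Rasgef1a, Fkbp10, Clec4g, Mcts2 and P3h4. Their log2 differences of males from females, adjusted for genotype, were -0.55, -0.93, -0.96, -0.60 and -1.04. For Jchain, Tnfrsf17 and Bhlha15, whose genotypes did not overlap, these were 1.03, 1.08 and 0.51. The genotype and sex differences are both taken against the same 3 wild-type females, so levels particular to those 3 would shift both alike.

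NF-kB target genes were shifted up in knockout spleens, with 5 of 47 rising and 0 falling, and 13 up and 4 down when adjusted over the list alone (median 0.16, adjusted p = 3.98e-04, and adjusted p = 0.651 with an estimated correlation). The cytokines Il6 and Il10 rose by 1.82 ± 0.30 and 1.30 ± 0.19, and the B cell activation marker Cd83 by 1.01 ± 0.19. The median was 0.15 with slide as a fixed term and 0.09 to 0.29 within slides. NF-kB pathway components had a median of -0.18 with 0 of 34 genes called (adjusted p = 0.0303). The list was called in 11 of 15 alternatives. Its call was lost with an estimated correlation (adjusted p = 0.783) and with slide as a fixed term (adjusted p = 0.451) or a random block (adjusted p = 0.124). Cell cycle genes were shifted up as a list, with a median of 0.62 over 39 genes (adjusted p = 4.23e-13, and adjusted p = 0.642 with an estimated correlation), although Pcna alone rose (0.45 ± 0.11, a call lost with slide as a fixed term) and 2 did when adjusted over the list alone. The median was 0.29 with slide as a fixed term and 0.08 to 1.42 within slides. Erythroid markers moved in the same direction (median 1.16, 0 of 23 called, adjusted p = 1.83e-05, and adjusted p = 0.783 with an estimated correlation), with 0.31 under a fixed slide term and 0.12 to 2.16 within slides. Neutrophil markers did so without slide terms (0.86, 0 of 20 called, adjusted p = 0.00639, and adjusted p = 0.783 with an estimated correlation), but their median was 0.02 with slide as a fixed term (adjusted p = 0.785) and -1.66 to 1.97 within slides.

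NK cell markers fell in knockout spleens, 11 of 23 with 0 rising, and 17 when adjusted over the list alone (median -0.72, adjusted p = 3.53e-11, and adjusted p = 0.292 with an estimated correlation). The receptors Klra8 (-1.49 ± 0.35, adjusted p = 0.101 with slide as a fixed term) and Klrb1c (-1.29 ± 0.22) fell. The median was -0.64 with slide as a fixed term and -0.65 to -0.30 within slides. Stromal and endothelial markers fell in 5 and rose in 1 of 27 cases (7 and 2 when adjusted over the list alone, median -0.52, adjusted p = 0.0184, and adjusted p = 0.292 with an estimated correlation), with the collagen Col4a2 (-1.49 ± 0.33, 6 of 7 wild-type spleens well above background) and the matrix protein Sparc (-1.42 ± 0.31) lower and Pdgfrb, a growth factor receptor, 0.77 ± 0.18 higher. The calls of Col4a2 (adjusted p = 0.0718), Sparc (0.0831) and Pdgfrb (0.0596) were lost with slide as a fixed term. Within slides, without adjustment for sex, the stromal median ran from -0.37 to 0.19, and the call was lost without the sex term (median -0.17, adjusted p = 0.450). The sex-adjusted fall is taken against the 3 wild-type females alone. Against the same 3, the list was also lower in wild-type males (median -0.54). Pro-B and pre-B cell markers rose in 2 of 14 cases, and in 3 with 2 falling when adjusted over the list alone (median 0.28, adjusted p = 0.0211, and adjusted p = 0.783 with an estimated correlation). Arpp21 rose by 2.38 ± 0.36 (5 of 7 wild-type spleens well above background) and Dntt, the terminal transferase of antigen receptor assembly, by 1.45 ± 0.34. The call of the list was lost with slide as a fixed term (adjusted p = 0.216), as was that of Dntt (adjusted p = 0.126).

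The other lists did not pass between genotypes. Of 29 break response genes, 2 rose and 2 fell (3 and 2 adjusted over the list alone, median 0.16, adjusted p = 0.0536, and called higher in 7 of 15 alternatives at adjusted p of 0.00641 to 0.292 overall), with Dclre1c (0.88 ± 0.15, but 0.38 and not called as the mean of its probes, adjusted p = 0.351) and Nbn (0.39 ± 0.09, not called with median centring, adjusted p = 0.0950) higher and Atm and Rad52 (-0.52 ± 0.09) lower. Of 31 p53 targets, 3 rose (3 up and 1 down adjusted over the list alone, median 0.02, adjusted p = 0.236), which were Gadd45a (0.98 ± 0.19), Tnfrsf10b (0.85 ± 0.16) and Btg2 (0.46 ± 0.10). T cell markers went both ways (2 up and 2 down of 24, or 4 and 3 adjusted over the list alone, median -0.11, mean 0.07, test direction up, adjusted p = 0.850), with Ctla4 2.37 ± 0.31 higher (6 of 7 wild-type spleens well above background) and Cd247, a T cell receptor chain, lower (-0.75 ± 0.13). ABC genes had 3 up and 1 down of 28 (4 and 1 adjusted over the list alone, median -0.03, mean 0.10, test direction up, adjusted p = 0.370), with the plasma cell regulator Prdm1 0.77 ± 0.15 higher and Il16 lower (-0.52 ± 0.12). MYC targets had 1 called gene, Odc1 (0.75 ± 0.11), NRF2 genes 1, Nfe2l2 (0.46 ± 0.10), and dendritic cell markers 1, Esam (-0.74 ± 0.18). The medians of these 3 lists were -1.70e-05, 0.08 and -0.11 (mean of the MYC list 0.04), their adjusted p 0.230, 0.0608 and 0.370, and adjusted over the list alone the dendritic cell list had 2 genes lower. The NRF2 list was called in 4 of 15 alternatives (adjusted p 0.0366 to 0.783), and the MYC list without a sex term (median 0.15, adjusted p = 3.11e-04). A fixed slide term removed the calls of Gadd45a (adjusted p = 0.0580), Btg2 (0.0624), Prdm1 (0.0605), Il16 (0.0959) and Nfe2l2 (0.0951), and Esam was not called with median centring (0.0716). No gene was called in the GCB, glycolysis, cholesterol, BCL2, interferon, MHC class II, MHC class I, B cell, germinal centre, macrophage and megakaryocyte lists, whose medians were -0.07, 0.09, -0.05, -0.08, -0.16, -0.11, -0.07, -0.16, -0.06, -0.24 and -0.05 (the BCL2 mean was -0.01 and its test pointed up). Their lowest adjusted p were 0.0679 for interferon and 0.0725 for macrophage markers, and the latter passed in 3 of 15 alternatives, among them slide as a fixed term (median -0.43, adjusted p = 2.08e-05). Myc (0.62 ± 0.18, adjusted p = 0.0749), Irf4 (0.48 ± 0.19, adjusted p = 0.176), Cdkn1a (0.30 ± 0.29, adjusted p = 0.595), Bcl6 (-0.06 ± 0.16), Trp53 (0.02 ± 0.15) and Cd3e (0.10 ± 0.18) did not pass.

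The genotype calls are from limma over the 13 spleens, and at an unadjusted p of 0.05 the count was 2807. The groups did not overlap for 173 genes that rose and 131 that fell, where chance gives 0.0583% of genes in each direction. The median over all genes was -0.05, and median centring gave 179 higher and 177 lower genes. With slide as a random block 361 rose and 462 fell, with slide as a fixed term 146 and 108, and within slides 87.0% to 100% of called genes kept their direction. These shares are partly built in, because the same samples called the genes. Values within slides are not adjusted for sex, and on 2 of the 5 slides the only wild-type spleen is male while the knockout spleens are female. None of the 9 lists that passed, 6 up and 3 down, did so with an estimated correlation. Only 3 wild-type females separate genotype from sex, and without the sex term 738 genes were higher and 693 lower.

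Between male and female spleens, adjusted for genotype, 7 genes were higher and 88 lower in males. This difference and the genotype difference are both taken against the same 3 wild-type females. Directions shared with the genotype comparison, as in the stromal, NK cell and plasma cell lists, are thus not separate results. Eif2s3y, Ddx3y and Kdm5d were well above background in 4 of 4 males and 0 of 9 females, and Xist in 9 of 9 females and 0 of 4 males, so no size is given for these differences. Stromal and endothelial markers were lower in males (0 up and 3 down of 27, or 9 down adjusted over the list alone, median -0.54, adjusted p = 0.0112, and adjusted p = 0.282 with an estimated correlation), with Sparc at -2.11 ± 0.34 and Igfbp7 at -1.51 ± 0.27. MYC targets (median -0.24, 0 called, 7 lower adjusted over the list alone, adjusted p = 1.91e-06) and NK cell markers (-0.24, 0 called, adjusted p = 0.0227) were shifted down and plasma cell markers up (0.08, 1 higher, 2 adjusted over the list alone, adjusted p = 0.0163). With an estimated correlation their adjusted p were 0.269, 0.974 and 0.974. Jchain, the plasma cell gene that passed, was 1.03 ± 0.18 higher in males. With slide as a fixed term the counts were 3 higher and 11 lower, and with slide as a random block 16 and 146.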

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

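Chosen after the results were seen were the test of the line 8 arrays against other lines, the tests of NK cell markers against B cell markers on and off chromosome 6, the test of the markers off chromosome 6 among females, and the span of 60 genes on each side of Atm. After seeing their results, the reading of the strain variant tests for NK cell markers and near Atm was also changed to leave these explanations open. For the former, a p above the threshold does not show that values did not differ. For the latter, 12 genes were too few to rank the shares. The other tests were chosen before. The count of called genes was compared with 100 splits of the samples, the real one included. The real split called 9681 genes for lymphoma lines against knockout spleens, and the highest other split 7158. For lines against wild-type spleens the counts were 9795 and 8155, and for knockout against wild-type spleens 525 and 5. In each case 1 split of 100 gave as many, the smallest share possible here, which argues against chance but does not exclude it. The splits ignored slide and the likeness of lines 4 and 5. Those of the spleens could place males in the knockout group, which the labels never do.

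The 2 arrays of line 8 were about as far apart as some arrays of different lines, with a correlation of 0.964, rank 13 of 45 pairs of lymphoma arrays. The difference between them at a probe had a correlation of 0.802 across 4174 genes with the difference at another probe of the same gene, which argues against noise of single spots. They were at least 2-fold apart at 2265 probes, and the 5 other pairs of arrays on their slide at 2447 to 3244. RNA of another line on 1 of these arrays and a difference between cultures of line 8 cannot be told apart, because the count lies close below that range and 3 pairs of different lines, 1 of them on a shared slide, had fewer such probes. A difference between cultures was not tested. Neither was a technical difference across a whole array, which also moves probes of a gene together, and no other sample has 2 arrays to size it.

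NK cell markers were lower in knockout spleens, with 8 of 10 called on chromosome 6 (median -1.05) and 3 of 13 elsewhere (-0.55). These medians are adjusted for sex. The differences tested below are of mean marker levels per spleen without a sex term, so their sizes cannot be set against these medians. Relative to B cell markers the chromosome 6 part differed by -0.77 (exact permutation p = 5.83e-04, 13 spleens), which argues against dilution by other cells as the cause of that part. For the other part the difference was -0.15 (exact permutation p = 0.217) over the 13 spleens. Among the 9 females it was -0.29 (exact permutation p = 0.0833), against -0.43 without B cell markers, so dilution stays open for it. A strain variant at the NK gene cluster on chromosome 6 stays open for the chromosome 6 part (same test, p = 0.217). Among the 9 females the other part differed by -0.43 (exact permutation p = 0.0238), a fall that a variant acting only on genes of the cluster would not give. This test restates the sex-adjusted fall of that part on the samples that set it, so it is no separate evidence. Among the 9 females the score of all 23 markers differed by -0.68 (exact permutation p = 0.0119, the smallest that 84 splits can give), which restates the sex-adjusted result on the samples that set it. Sex does not differ among these 9, so it cannot set that difference. The markers were also lower in males (median -0.24, list test adjusted p = 0.0227, and adjusted p = 0.974 with an estimated correlation). That fall is taken against the same 3 wild-type females, so it adds no separate evidence. An effect of Atm loss on NK cells stays open beside dilution and a strain variant and was not tested apart from them.

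Of the 120 tested genes nearest to Atm on chromosome 9, 12 were called between genotypes (6 higher and 6 lower, among them Mpzl2 and Fam219b), which is 10% against 3.76% of other genes (Fisher's exact p = 0.00208). Of 11097 windows of as many genes elsewhere, 1.59% held as many called genes, up to 23, which argues against clusters as common as this one anywhere in the genome. Strain variants carried along with the targeted allele may explain the cluster. If so, the neighbours should keep their direction in the lines, and 7 of 12 did (58.3%), against 346 of 512 called genes elsewhere (67.6%, one-sided Fisher's exact p = 0.839). With 12 genes this leaves strain variants open, and an effect of Atm loss on its neighbours was not tested.

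Single samples stood apart from the rest of their group in 51 of 552 sets of values for the genes and lists described, where chance flags about 1 in 20 groups. Such a sample lay beyond the others of its group by more than Dixon's limit, and its value is given here as a log2 level with no explanation tested. Lymphoma line 3 was higher than the other lines for Alas2 (-3.89), C1qc (-5.06), Ccl5 (-1.23), Gzma (-4.36), Hba-a1 (0.97), Klrd1 (-5.31), Oas1a (-2.94), S100a8 (-3.71), S100a9 (0.28), Tgfbi (-4.63) and Treml4 (-5.25) and lower for Mpzl2 (-4.62). Without line 3, 5656 genes were higher and 3953 lower against knockout spleens. Line 7 was higher for the NK cell marker score (-5.44), Esam (-3.08), Ltbr (-5.31), P3h4 (-3.39), Pde4d (-6.15) and Thy1 (-5.06), and without it 5698 genes were higher and 3991 lower. Ltbr, Pde4d and Thy1 were well above background in 0 of 9 lines, so their levels there have no order. Of the 23 NK cell markers, 10 were well above background on no lymphoma array, so that score is partly a background level. The array of line 7 also had the highest median signal of the lymphoma arrays (40.3). Line 9 was higher for Calca (-2.54) and Igfbp7 (-4.15) and lower for Tcf4 (3.64). Line 1 was lower for Plch2 (4.39), line 5 higher for Ldha (7.81) and line 6 lower for Il16 (1.80).

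Wild-type replicate 2, a male, was higher than the other wild-type spleens for the pro-B and pre-B cell (0.90), neutrophil (4.17) and megakaryocyte (-0.47) scores and for Camp (6.93), Fdps (0.82), Foxm1 (0.24), Ltf (7.48), Mpzl2 (-3.79), S100a8 (7.07), Slc2a3 (3.11) and Tnfrsf1a (2.72), and lower for Atm (-0.67), Bmf (1.77), Fcer2a (3.07) and Mef2b (-6.17). Without it 261 genes were higher and 309 lower between genotypes, and the break response (adjusted p = 0.0386) and NRF2 (adjusted p = 0.0467) lists passed. The sex-adjusted medians did not move, since the females alone set them. Wild-type replicate 5 was higher for Batf (2.49) and Cth (-5.35), replicate 4 lower for Ncan (-6.42) and replicate 6 lower for Gcsam (-6.16), both not well above background there. Knockout replicate 4 was higher for Fkbp5 (-0.70) and Lmo2 (2.77) and lower for Gnaz (-5.90), Phlda3 (-1.55), S100a9 (7.50) and Wwtr1 (-8.75, not well above background). Knockout replicate 1 was higher for Sdc1 (0.60) and replicate 5 lower for Zfp3 (-2.82).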

How the results depend on the processing

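Chosen after the data were seen were the normexp correction on median signals, which replaced a planned one on mean signals that the files do not hold and that was not run, and the fits without wild-type replicate 2 and without lines 3, 5, 7 and 8. The other alternatives were chosen before the data were examined. No paired analysis was possible because replicate numbers follow the order of deposit and pair no samples. Over all alternatives, 46 of the counts and other values moved, which means by more than 1.5 times for a count and by 1 SD or more for another value, and 264 changed by less or not at all, 54 list results lost and 23 gained a call while 1381 did neither, and of the named genes 13 reversed, 57 lost and 9 gained a call while 3240 did neither. A result that passed under neither setting counts among the last even where its sign changed. The cause of these changes was not tested. Median centring moved the median of all genes from 0.18 to 0.83 against knockout spleens, so the 7 reversals found with it, of the 13, do not show a reversal relative to other genes.

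With arrays centred on medians, 8691 genes were higher and 2509 lower in the lines than in knockout spleens, and 8546 and 2636 against wild-type spleens. The overlap was 8212 up and 2341 down, and 177 genes were lower between genotypes. Against knockout spleens Atm was -0.29 (adjusted p = 0.238), Dclre1c 0.092, B2m 0.24, Irf4 0.025 and Trp53 0.57, which passed, and against wild-type spleens Hk1 was 0.23, Irf4 0.60 and Trp53 0.54. With normexp and quantile normalisation Smarca4 was -0.21 against knockout and -0.11 against wild-type spleens, Vim -0.16 against wild-type spleens, and 11 genes were higher in males. With quantile normalisation of the processed signal, Smarca4 was -0.17 and -0.075 and Vim -0.17. The median ratio of the SD of the lines to that of knockout spleens was 1.84 as reported, 1.75 with normexp, 1.76 with quantile normalisation and 1.94 with median centring.

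With every probe tested on its own, 10386 probes were higher and 8444 lower against knockout spleens, 10171 and 9170 against wild-type spleens, and 467 and 535 between genotypes. The overlap was 9399 and 7889, 20 probes were higher in males, and the SD ratio was 1.77. A stricter filter left 3 genes higher in males. With slide as a random block, 361 genes were higher and 462 lower between genotypes, and 16 and 146 in males. With slide as a fixed term the counts were 146 and 108, and 3 and 11. Array weights gave 14 higher and 139 lower in males. Without a sex term 738 genes were higher and 693 lower between genotypes, in females alone 163 and 176, and in 1 fit of all groups, also without a sex term, 130 and 119.

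With an estimated correlation, 0 lists were called higher and 5 lower in each lymphoma comparison, and 0 and 0 between genotypes. The NF-kB targets (-0.55 and -0.67) then had adjusted p of 0.215 and 0.291 in the lymphoma comparisons. The SD ratio was 1.90 with the 10 lymphoma arrays as 10 samples and 1.63 without the lines of the lymphoma-only slide. It was 1.78 without line 7 and 1.85 without line 8.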

Other observations

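The following was looked at after the values were seen. Line 4 and line 5 were the most alike of all pairs of different lines, with a correlation of 0.986 and 789 probes at least 2-fold apart, where the pairs of different lines ran from 789 to 4828 probes. They may come from 1 mouse or related tumours, so the 9 lines may hold fewer independent samples. Without line 5, 5643 genes were higher and 4013 lower against knockout spleens. In the lines, whose sex is not in the labels, Xist was high in lines 3, 6, 7, 8 and 9, and Y-linked genes were high in lines 2, 4 and 5. Line 1 had Eif2s3y at 2.80 and Kdm5d at -0.73, but Ddx3y and Xist were not well above background. Whether part of the Y chromosome is missing in line 1 was not tested.

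Cd3e and its neighbour Cd3g were both higher in the lines than in knockout spleens (1.87 ± 0.24 and 7.35 ± 0.78), in mice that lacked Cd3e. Which transcripts the probes read in the targeted region was not tested.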
